A study of Mus musculus with 2 samples.

How the data were processed

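Pancreatic tumours of PKT mice were profiled by droplet single-cell RNA sequencing. These mice carry a Ptf1a-driven Cre recombinase, a Cre-activated Kras G12D oncogene and floxed alleles of the TGF-beta receptor gene Tgfbr2. Per the labels, 3 mice received the vehicle and 3 mice the p38 MAPK inhibitor ARRY-614 for 2.5 weeks from 4 weeks of age, and the 3 tumours of each treatment were pooled into 1 library. The barcodes carry no record of the mouse, so each group was 1 sample. Libraries were made with the 10x Genomics 3' v3 kit, per the labels' protocols. The same protocols speak of nuclei taken from single-cell suspensions, while the median barcode held 3.83% mitochondrial UMIs (unique molecular identifiers) in the vehicle library and 3.84% in the ARRY-614 library. The word cell is used here for a barcode.

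The deposited files of each library were a count matrix, its barcodes and its gene features. The deposited values are whole-number UMI counts per gene and barcode, not normalised, per the file headers and the values. The submitters' processing notes name Cell Ranger, STAR and the genome build mm10. Per the file headers, the vehicle matrix was made with Cell Ranger version 3.1.0 and the ARRY-614 matrix with version 4.0.0. The vehicle feature table listed 31053 genes and that of ARRY-614 listed 32285. The tables shared 30406 gene identifiers, of which 597 had another symbol in the other table, while 647 identifiers stood only in the vehicle table and 1879 only in the ARRY-614 table. Software version, feature table and treatment therefore cannot be told apart. Only shared identifiers were used, and they held 99.9% of the vehicle UMIs and 99.6% of the ARRY-614 UMIs. Every shared identifier was found in GENCODE M21 on GRCm38 (mm10), which gave coordinates, exon lengths and overlaps between exons of different genes on the same strand. Levels of genes with such an overlap are uncertain, because a read in the shared stretch can be counted or dropped depending on which of the genes the feature table lists. The same holds for genes with near-identical copies, such as Hspa1a and Hspa1b.

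Barcodes with under 500 genes (1034 vehicle, 577 ARRY-614) or with 20% or more mitochondrial UMIs (1403 vehicle, 598 ARRY-614) were removed. Doublets were scored with Scrublet through scanpy, and the highest scores of each library were removed at 0.8% per 1000 barcodes. This marked 1235 vehicle barcodes (9.94%) and 438 ARRY-614 barcodes (5.92%). The kept cells numbered 9551 (135482326 UMIs, median 8618 per cell) and 6230 (82491771 UMIs, median 8538 per cell). Both libraries were clustered together without integration. Counts per 10000 were log-transformed, 2000 variable genes and 30 principal components were taken, and a shared-neighbour graph over 15 neighbours was partitioned with the Leiden algorithm at resolution 1.0 and seed 0.

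The 30 clusters were named from marker lists fixed in advance. A marker counted as detected in a cluster when at least 25% of its cells had a UMI and its level was at least 2-fold that of all other cells. A cluster took the class with the largest detected share of its markers. It stayed unnamed with under 3 detected markers, with more markers of another class among its 10 leading genes, or with a median UMI count under that of its library divided by 3 together with under 2 own markers among those genes. It also stayed unnamed when a different class reached 75% of the best class's share while under 2 own markers stood among those genes. The demand for 2 own markers and this last condition were set after the first clusters had been seen, and the unnamed clusters held 2.31% of vehicle cells and 2.63% of ARRY-614 cells. Classes are written as "X-like", since they rest on rebuilt names and not on an annotation by the authors.

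UMI counts were summed per class and library and scaled to CPM, counts on a common total, with trimmed-mean (TMM) factors from edgeR 4.0.16 in R 4.3.3. A log2 ratio is the ARRY-614 level over the vehicle level, so negative values are lower in the ARRY-614 library. Ratios have 95% conditional exact binomial intervals, single sums exact Poisson intervals and shares of cells exact Clopper-Pearson intervals. All of these cover counting error only. Where a library had 0 UMIs the ratio was set against a floor of 3 counts, and the exact interval gives its bound. No test across samples was possible with 1 library per group, so no p-value was computed. The genes were summarised by 36 lists fixed in advance, each in the classes it was meant for, using members with at least 10 UMIs over both libraries. The text gives the number of measured members that differed by at least 1.5-fold, the median log2 ratio with a range from 1000 Poisson draws, and the percentile of that median among 10000 random lists of the same size matched on mean expression. The range was widened where needed to reach the reported median. The percentile describes these libraries. The lists meant for endothelial-like and acinar-like cells were not computed there for want of cells. Where shares of cells with a UMI were compared, each cell was also thinned to 1000 UMIs, and shallower cells were left out.

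Genes named in the text followed a rule fixed in advance. It took Il1a, Il1b, Il1rn, Il1r1, Mapk14, Cxcl1, Il6 and Acta2. It took up to 2 members with the highest and 2 with the lowest ratios of each list, with at least 30 UMIs, a 1.5-fold ratio and an interval that left out no difference. It also took the 8 highest and 8 lowest ratios of all genes in each class with at least 50 cells per library. Such genes needed at least 100 UMIs in the higher library, a 2-fold ratio of the same sign under every scaling, a level there of at least 50% of that in any other class, and 1 symbol in both tables. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, Xist, Y-linked genes, unnamed gene models and acinar enzymes were left out. After the values had been seen, this last part was repeated without genes that overlap another gene, genes at least 4-fold shifted the same way in 6 classes, genes with UMIs in under 10 cells of the higher library and genes with over 25% of those UMIs in a single cell. Values from the repeat are marked as such. Genes that are named outside these rules are said to have been chosen after their values were seen.

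The step that computes ratios, intervals and list percentiles was tested on simulated Poisson counts with 200 changed genes. For the macrophage-like class (14649 genes), 95.3% of intervals of unchanged genes held the true ratio, as did 97.0% for 2-fold and 95.0% for 4-fold changes. For the epithelial-like class (13827 genes) these shares were 95.7%, 96.0% and 96.0%. The intervals assume Poisson counts too, so these shares check the computation only. They do not show coverage for real UMIs, which can gather in few cells. Other settings were also tried. They were looser and stricter cell filters, no doublet removal, other clustering resolutions, clustering each library by itself, no TMM factors, DESeq2 1.42.0 size factors, equal weight per cell, other gene totals, other count minimums, thinning, and centring within bins of exon length. Those added after the data were seen were the largest shared cluster of each class, totals without Gm42418 and AY036118, shares over non-lymphoid cells, and clustering without overlapping genes. Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.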

Results

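The data were 2 libraries of pooled pancreatic tumours from PKT mice, 1 from vehicle-treated and 1 from ARRY-614-treated animals. The vehicle library held 12426 barcodes and 166523869 UMIs with a median of 6228 per barcode, and the ARRY-614 library held 7400 barcodes and 93311854 UMIs with a median of 8035. The question named in the study's title is whether p38 MAPK signalling in tumour cells drives inflammation of the stroma through IL-1 alpha, the cytokine encoded by Il1a. Cells from 3 mice were pooled in each library and the spread between mice is unknown. No difference below has a replicate check, and each one compares these libraries, not the treatments.

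Fibroblast-like and epithelial-like cells took smaller shares of the ARRY-614 library, and B cell-like and T cell-like cells larger ones. Fibroblast-like cells made up 9.31% (95% interval 8.73 to 9.91, 889 cells) of the vehicle library and 0.305% (0.184 to 0.476, 19 cells) of the ARRY-614 library, a log2 ratio of -4.93 (-5.67 to -4.28). Epithelial-like cells, which were not sorted into carcinoma and other duct cells, made up 6.61% (6.12 to 7.12, 631 cells) and 1.89% (1.57 to 2.26, 118 cells), a log2 ratio of -1.80 (-2.10 to -1.52). The endothelial-like share was 0.712% (68 cells) against 0.177% (11 cells), a log2 ratio of -2.01 (-3.08 to -1.08). B cell-like cells were 12.7% (1213 cells) and 27.3% (1702 cells), a log2 ratio of 1.11 (0.998 to 1.21), and T cell-like cells 5.95% (568 cells) and 12.5% (778 cells), a log2 ratio of 1.07 (0.91 to 1.23).

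Macrophage-like cells were the most frequent class in both libraries, at 37.1% (3547 cells) and 31.1% (1935 cells), followed in the vehicle library by neutrophil-like cells at 21.5% (2054 cells) against 19.1% (1189 cells). Their log2 ratios of -0.26 (-0.34 to -0.18) and -0.17 (-0.28 to -0.07) turned to 0.19 and 0.27 when B, plasma and T cell-like cells were taken out of the denominator. Dendritic cell-like cells were at 2.38% (227 cells) and 3.76% (234 cells). The log2 ratios of plasma cell-like cells (87 and 64 cells), mural-like cells (27 and 8) and acinar-like cells (19 and 8), the enzyme-secreting cells of the pancreas, had intervals that held 0. The fibroblast-like log2 ratio was -4.49 (-5.23 to -3.84) over that denominator without B, plasma and T cell-like cells, and -3.42 when each library was clustered by itself.

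**Figure D1:**
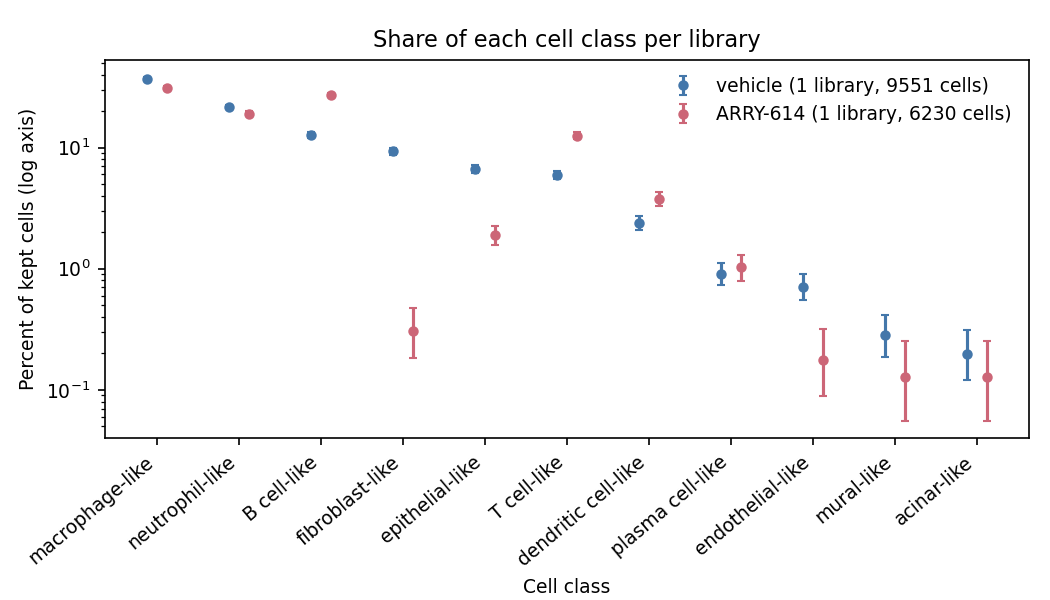
Share of kept cells in each named class, in percent on a log axis, for the vehicle library (9551 cells) and the ARRY-614 library (6230 cells). Points are shares and bars are 95% Clopper-Pearson intervals, which cover counting error only. The fibroblast-like class stands at 9.31% and 0.305%.

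In the epithelial-like class, the secreted cytokines fixed as a list were mostly lower in the ARRY-614 library. Of 20 measured cytokine genes 11 were at least 1.5-fold lower and 3 at least 1.5-fold higher. The median log2 ratio was -0.90 (-1.39 to -0.85), at percentile 0 of the random lists. Il1a (chromosome 2, 129299610 to 129309972 on mm10, minus strand) was at 31.1 CPM in the vehicle library, from 595 UMIs in 135 cells, and at 11.3 CPM in the ARRY-614 library, from 35 UMIs in 15 cells. Its log2 ratio was -1.46 (-1.999 to -0.97). Cxcl1 (chromosome 5, 90891241 to 90893115, plus strand), which encodes a neutrophil chemoattractant, was at 60.6 and 16.7 CPM, a log2 ratio of -1.86 (-2.29 to -1.46), and Ccl20, a chemokine, had a log2 ratio of -3.43 (-5.31 to -2.05). Il1b at 1.62 (1.40 to 1.83) and Cxcl3 at 2.23 (1.71 to 2.74) went the other way, the latter from 57 ARRY-614 UMIs in 5 cells with 50.9% in a single cell. Il1b rested on 281 ARRY-614 UMIs in 30 cells. The share of cells with an Il1b UMI was 36.9% in the vehicle and 25.4% in the ARRY-614 library. Its vehicle level of 29.5 CPM lay below the 52.1 CPM of B cell-like cells. In the epithelial-like class the neutrophil calprotectin gene S100a8, chosen after its values were seen, also stood at 466 CPM in the ARRY-614 library against 43.8 CPM in the vehicle library. The fibroblast gene Col1a1, chosen likewise, went from 79.5 CPM in the vehicle to 2.57 CPM in the ARRY-614 library. RNA of other cells in this class thus differed between the libraries. With cells thinned to 1000 UMIs the log2 ratio of Il1a was 1.35, from 10 vehicle and 4 ARRY-614 cells with a UMI, and the cytokine median was -0.20. With equal weight per cell Il1a was at -0.26 and Cxcl1 at -1.16.

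Immediate early, heat shock, proliferation, classical subtype and senescence secretory genes of the epithelial-like class were mostly lower as well. The AP-1 and immediate early genes, transcription factors induced within minutes of a stimulus, had a median of -0.86 with 10 of 18 lower and 0 higher, led by Atf3 at -2.21 and Fosb at -2.10. Heat shock and dissociation stress genes had a median of -0.92 with 11 of 15 lower, and the inducible chaperone gene Hspa1a was at -3.84 (-4.30 to -3.41). Proliferation genes had a median of -0.73 with 16 of 27 lower, among them the mitotic kinase genes Aurka at -1.81 and Aurkb at -2.02. The classical subtype list of pancreatic carcinoma had a median of -0.64 with 12 of 23 lower, including the secreted proteins Agr2 at -2.24 (-2.46 to -2.04) and Tff3 at -2.69 (-3.50 to -1.97). The senescence secretory list had a median of -0.86 with 8 of 13 lower and 1 higher. All 5 of these medians lay at percentile 0.

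Targets of NF-kB had an epithelial-like median of -0.49 (-0.59 to -0.28) with 6 of 19 lower and 1 higher, at percentile 0.15. Among them were the adhesion gene Icam1 at -1.42 and Ier3 at -0.90, while Tnfaip2 was at 0.68, and the median turned to 0.18 after thinning. Hypoxia and glycolysis genes went the other way, with a median of 0.19, 8 of 22 higher, 0 lower and percentile 99.7, and the mitophagy gene Bnip3 at 1.47 (1.17 to 1.77). The p38 MAPK pathway genes had a median of -0.02 at percentile 66.2. Mapk14, which encodes p38 alpha, was at 23.7 and 28.0 CPM, a log2 ratio of 0.24 (-0.11 to 0.58). The median of the ERK output list was -0.17 and that of the interferon response list -0.30, at percentiles 28.9 and 5.69. Medians of JAK-STAT3 output (-0.42), the unfolded protein response (-0.36), epithelial identity (-0.28), TGF-beta response (-0.22), mesenchymal genes (-0.18), basal subtype (-0.14), apoptosis and p53 (-0.12), class I presentation (-0.02), acinar enzymes (0.04) and IL-1 receptor signalling (0.23) lay between percentiles 1.10 and 93.2.

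The extreme single genes of the epithelial-like class rested on few cells. Among the highest ratios under the naming rule were the gut and islet hormone genes Gast, Ppy, Ghrl, Cck, Ins2 and Pyy, and at least 51.1% of the ARRY-614 UMIs of each came from a single cell. The lowest ratio, that of the hormone gene Sst, rested on 4088 vehicle UMIs in 4 cells against 0 UMIs. In the repeat without such genes, the lowest ratios were those of the phospholipase gene Pla2g10 (5.27 against 0.322 CPM, log2 ratio -4.03, interval -9.35 to -1.52), Teddm3 (185 UMIs against 2), Ly6k (201 UMIs against 0), Nccrp1, Gdf15, Spink4, Krt17 and Lypd8. Gdf15, a stress-induced cytokine of the TGF-beta family, was at 44.9 and 6.76 CPM, a log2 ratio of -2.73 (-3.43 to -2.11).

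The fibroblast-like class was compared as 889 cells against 19, so each ARRY-614 value rests on very few cells. The inflammatory fibroblast (iCAF) list was lower in the ARRY-614 library and the contractile myofibroblast (myCAF) list was near the other genes. Of 36 iCAF genes 22 were at least 1.5-fold lower and 2 higher, with a median of -0.87 (-1.08 to -0.76) at percentile 0. Of 30 myCAF genes 8 were lower and 2 higher, with a median of -0.14 (-0.24 to -0.03) at percentile 30.4. Il6 (chromosome 5, 30013114 to 30019981, plus strand) was at 65.7 CPM from 1756 UMIs in 326 cells and at 25.5 CPM from 22 UMIs in 5 cells, a log2 ratio of -1.37 (-2.04 to -0.76). Cxcl1 had 2251 UMIs in 262 cells against 0 UMIs, so its log2 ratio had a 95% upper bound of -4.30. Acta2 (chromosome 19, 34241090 to 34255590, minus strand), the smooth muscle actin gene of myofibroblasts, was at 2648 and 2545 CPM, a log2 ratio of -0.06 (-0.12 to 0.00).

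Other fibroblast-like medians were -1.23 for the cytokine list (13 of 16 lower), -1.08 for AP-1 and immediate early genes (14 of 18), -1.01 for heat shock genes (8 of 15), -0.84 for NF-kB targets (13 of 19) and -0.75 for JAK-STAT3 output (9 of 17), all at percentile 0. The antigen-presenting fibroblast (apCAF) list had a median of -0.61 (-1.20 to -0.26) with 7 of 13 lower and 4 higher, and the extracellular matrix list a median of -0.29 with 10 of 31 lower. Proliferation genes had a median of 0.81 with 16 of 27 higher, and hypoxia and glycolysis genes 0.36 with 9 of 21 higher. The iCAF median was -1.47 when each library was clustered by itself. The myCAF median was 0.001 after centring on exon length and -0.76 when each library was clustered by itself, and the apCAF median was 0.42 in the latter setting and 0.04 after thinning.

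In the macrophage-like class, inflammatory cytokines and immediate early genes were lower in the ARRY-614 library, while the medians of the monocyte and antigen presentation lists were higher. Of 23 inflammatory genes 17 were at least 1.5-fold lower and 1 higher, with a median of -1.23 (-1.55 to -1.18). Of 18 AP-1 and immediate early genes 16 were lower and 0 higher, with a median of -1.51 (-1.53 to -1.48). Il1a was at 97.9 and 12.2 CPM, a log2 ratio of -3.01 (-3.15 to -2.87), and Il1b at 1031 and 258 CPM, a log2 ratio of -2.001 (-2.03 to -1.97). The pools differed in the sex of the mice, by Xist and Y-linked genes. Without TMM factors, Il1b was at -3.11 in male and -1.34 in female cells of this class. Cxcl1 was at -4.08 (-4.24 to -3.92), the chemokine gene Ccl4 at -3.13, Il6 at -2.39 and Atf3 at -3.12. The suppressive list had a median of -0.58 (-0.60 to -0.55) with 13 of 26 lower and 0 higher, including the scavenger receptor gene Marco at -3.78 (-3.97 to -3.59). All 3 medians lay at percentile 0.

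Monocyte genes had a median of 0.60 with 7 of 13 higher and 3 lower in the macrophage-like class. Plac8 at 2.05 (2.02 to 2.08) and Ly6c2 at 2.07 (1.97 to 2.18) were higher and Chil3 at -2.86 lower. MHC class II genes had a median of 0.59 with 4 of 8 higher, and their transactivator gene Ciita was at 1.24 (1.06 to 1.42). The class I presentation median was 0.43 with 5 of 15 higher, and the interferon response median 0.45 with 8 of 25 higher. These 4 medians lay at percentile 100. Heat shock genes (-0.69, 10 of 15 lower), proliferation genes (-0.73, 15 of 27 lower), NF-kB targets (-0.32, 7 of 19 lower) and hypoxia and glycolysis genes (-0.22, 1 of 22 lower) lay at or below percentile 0.080. Gdf15 had a log2 ratio of -5.81 (-6.49 to -5.21), and Cd5l, a macrophage scavenger protein gene, one of -4.41 (-5.22 to -3.69). Of the 8 highest ratios under the naming rule, 7 belonged to genes that overlap another gene, such as Rnasek, Apoc2 and Nme2, so their values are uncertain.

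Different clusters held most macrophage-like cells in the libraries. Cluster 2 (leading genes Lyve1, Cd163, Fcna) held 28.8% of the class in the vehicle library and 13.9% in the ARRY-614 library, and cluster 5 (Apoc2, Ccr2, S100a4) 6.03% and 50.2%. Cluster 7 (Mmp12, Cxcl3, Arg1), with Cxcl1 and Il1a among its 10 leading genes, held 24.6% and 7.55%, and cluster 12 (Ms4a4c, Ccr2, Vcan) 12.1% and 0.362%. Clusters 5 and 12 share leading genes such as Ccr2, S100a4 and Ms4a4c. Atp6v0c and Fam89b, also leading genes of cluster 5, were at least 4-fold higher in the ARRY-614 library in all 6 classes examined. Without integration, these shares cannot be told from a split of like cells by library. Within cluster 4 (Cx3cr1, Fcrls, Ms4a7; 775 and 426 cells), the largest shared cluster, Il1a was at -2.37 and the inflammatory median at -2.05. The suppressive median there was -0.20, and it was -0.30 when each library was clustered by itself.

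In the neutrophil-like class, the cytokine genes Il1a, Cxcl1, Tnf and Il23a were lower in the ARRY-614 library, while the list of suppressive neutrophils (PMN-MDSC) went both ways. Il1a was at 198 and 31.3 CPM, a log2 ratio of -2.66 (-2.87 to -2.45). Without TMM factors its log2 ratio was -2.73 in the class, -3.82 in male and -1.22 in female cells. Il1b, the most abundant of these cytokines, was at 12140 and 4805 CPM, a log2 ratio of -1.34 (-1.36 to -1.32). Cxcl1 was at -4.57 (-5.18 to -4.02), Tnf at -3.15 (-3.31 to -2.99) and Il23a at -3.28 (-3.75 to -2.83). The stimulus-induced transcription factor genes Nr4a1 and Jun were at -2.74 and -2.45 in the repeat. Of 30 PMN-MDSC genes 10 were lower and 8 higher, with a median of -0.08 (-0.24 to 0.01) at percentile 29.8, Ly6g at 1.39 and Ccl3 at -2.62. The PMN-MDSC median was -0.45 within cluster 3 (leading genes Asprv1, Cxcr2, Hdc) and 0.07 under the stricter cell filter.

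The share of cells with an Il1a UMI followed the same direction in the myeloid classes. It was 28.1% of macrophage-like cells in the vehicle library (median depth 15540 UMIs) and 8.84% in the ARRY-614 library (18674 UMIs), and 19.9% against 6.90% of neutrophil-like cells (2867 and 4515 UMIs). In B cell-like cells, taken as the background, it was 1.15% (3931 UMIs) and 0.235% (6768 UMIs). After thinning to 1000 UMIs these shares were 6.32% and 0.933% in macrophage-like cells, 11.03% and 2.05% in neutrophil-like cells, and 0.417% and 0.118% in B cell-like cells. Thinning left out 50 and 5, 23 and 16, and 14 and 6 cells of these classes. In the epithelial-like class the share was 21.4% (23395 UMIs) and 12.7% (19832 UMIs), and 1.62% and 3.39% after thinning, which left out 13 and 0 cells.

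Il1rn, which encodes the antagonist of the IL-1 receptor, was also lower in the ARRY-614 library. Its log2 ratio was -1.18 (-1.24 to -1.11) in macrophage-like, -0.86 (-0.92 to -0.80) in neutrophil-like and -0.46 (-0.66 to -0.27) in epithelial-like cells, and -0.81 (-3.88 to 1.07) in fibroblast-like cells from 109 UMIs against 2. The receptor gene Il1r1 was at -0.56 (-0.88 to -0.25) in fibroblast-like cells (149 CPM in the vehicle library), at -2.62 (-3.28 to -2.02) in macrophage-like and -1.40 (-2.20 to -0.65) in neutrophil-like cells. Few myeloid cells held an Il1r1 UMI, 4.71% (vehicle) and 1.09% (ARRY-614) of macrophage-like and 2.53% and 1.51% of neutrophil-like cells. In B cell-like cells, the background, the shares were 1.65% and 0.294%. The myeloid Il1r1 ratios therefore cannot be told from a difference in free RNA. In epithelial-like cells Il1r1 was at 1.67 (1.14 to 2.18), from 49 ARRY-614 UMIs in 11 cells, of which 61.2% came from a single cell.

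**Figure D2:**
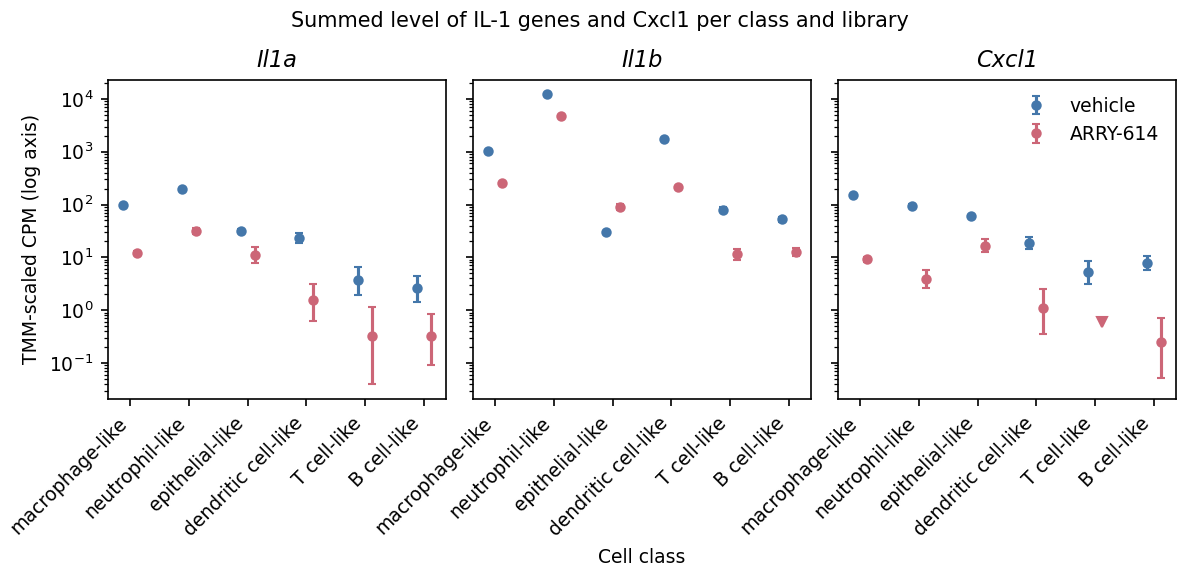
TMM-scaled CPM of Il1a, Il1b and Cxcl1 on a log axis in the summed counts of 6 classes, for the vehicle and the ARRY-614 library (1 library each). Bars are exact 95% Poisson intervals and the triangle is the upper limit for a sum of 0 UMIs. Il1a in macrophage-like cells stands at 97.9 and 12.2 CPM. Il1b in epithelial-like cells is higher in the ARRY-614 library (90.4 against 29.5 CPM), from 281 UMIs in 30 cells.

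In the T cell-like class, interferon response genes were higher in the ARRY-614 library and regulatory and checkpoint genes lower. Of 24 interferon response genes 20 were at least 1.5-fold higher and 0 lower, with a median of 1.26 (1.12 to 1.49) at percentile 100. The antiviral genes Ifit1 and Ifit3 were at 3.44 (2.95 to 3.97) and 3.097 (2.54 to 3.71). Of 11 regulatory T cell genes 10 were lower, with a median of -1.28 (-1.42 to -1.15), and of 11 exhaustion and checkpoint genes 9 were lower, with a median of -1.26 (-2.06 to -0.98). Pdcd1, which encodes the checkpoint receptor PD-1, was at 126 and 19.3 CPM, a log2 ratio of -2.70 (-3.01 to -2.41), and Ctla4 at -1.94. The regulatory-like cluster 11 (Izumo1r, Ctla4, Ikzf2) held 45.4% of the class in the vehicle library and 26.4% in the ARRY-614 library. Of all kept cells, however, it held 2.70% (2.39 to 3.05) and 3.29% (2.86 to 3.76). Cluster 10 (Lef1, Tcf7, Bcl11b) held 1.79% and 5.875% of all kept cells, so its larger share lowered that of cluster 11 within the class. Within cluster 11 Pdcd1 was at -2.05 and Ctla4 at -1.41.

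The cytotoxic list of the T cell-like class had a median of -0.29 (-0.51 to -0.22) with 7 of 18 lower and 1 higher, at percentile 0.24, with Klrg1 at -3.55 and Eomes at 0.78. It was -0.60 without doublet removal. Naive and memory genes had a median of 0.32 at percentile 98.9, with the homing receptor gene Sell at 0.90. Heat shock genes (-0.40, 5 of 15 lower) and proliferation genes (-0.75, 15 of 25 lower) lay at percentile 0, with Hspa1b at -4.82 (-5.38 to -4.31). Without TMM factors the median log2 ratio of all genes was -0.195 in the T cell-like, -0.123 in the B cell-like and 0.305 in the plasma cell-like class.

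Among the genes that passed the naming rule in the B cell-like class, the lowest ratios were those of the heat shock genes Hspa1a at -7.17 (-8.08 to -6.39) and Hspa1b at -6.12 (-6.63 to -5.65). In the repeat, which left out Hspa1a, Hspa1b was followed by Jund at -1.77, Myc at -1.55 and the activation marker gene Cd69 at -1.51. Most of this class lay in cluster 6 (leading genes Fcmr, Ighd, Cd79a; 1085 and 70 cells) in the vehicle library and in cluster 1 (Ighd, Bank1, Fcmr; 122 and 1593 cells) in the ARRY-614 library. These clusters share leading genes and were formed without integration, so they may split like cells by library. Within cluster 1, Myc was at -0.68 and Cd69 at -0.73. In the dendritic cell-like class Ccl4 was at -5.83 (-6.31 to -5.40), Nr4a2 at -3.21 and Hspa1b at -3.29. In the plasma cell-like class Asns at -1.93, Atf5 at -1.71 and the chaperone gene Hspa5 at -1.49 were lower, and the trafficking adaptor gene Ndfip1 was at 1.42.

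Over all 7 classes compared gene by gene, 44 of the 56 highest ratios under the naming rule and 8 of the 56 lowest belonged to genes that overlap another gene. Of 8124 genes measured in 6 classes, 31 were at least 4-fold higher and 22 at least 4-fold lower in all of them. Of the 31, 25 (80.65%) overlap another gene, as do 8 of the 22 (36.36%), against 9.66% of all 8124 genes measured. The 22 included the collagen gene Col1a1, the proteoglycan gene Dcn, Hspa1a, Atf3, Fosb and Ccl3, and Rps6ka4, a kinase gene of the p38 list that overlaps another gene. In repeats without these genes, Pik3ap1 was at 3.07 (2.93 to 3.21) in macrophage-like and 3.06 (2.73 to 3.41) in neutrophil-like cells, and the histone gene Hist1h4h was at 3.19 in epithelial-like, 2.70 in T cell-like and 2.53 in B cell-like cells. Each of these genes shifted the same way in unlike classes, so a difference between the runs cannot be told from a change in the cells.

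**Figure D3:**
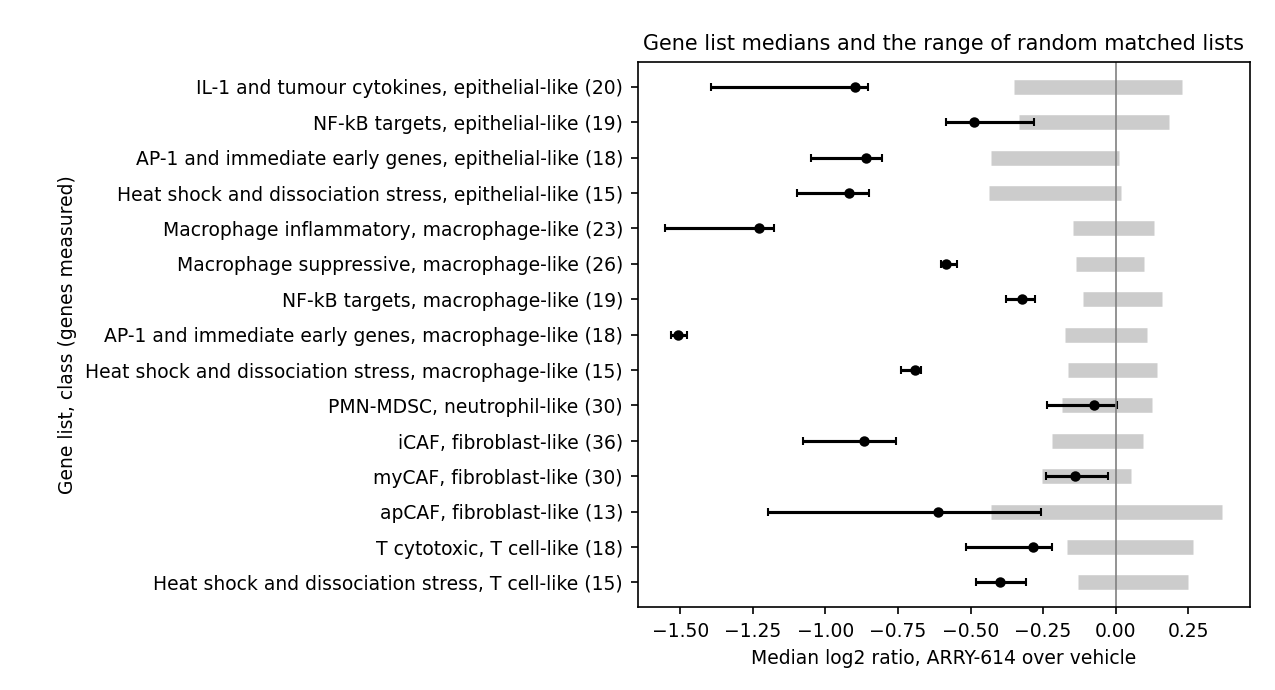
Median log2 ratio, ARRY-614 over vehicle, of gene lists in the class named on the vertical axis, with the number of genes measured. Black bars hold 95% of the medians over Poisson draws of the counts, widened where needed to reach the reported median. Grey bars hold 95% of 10000 random lists matched on expression. The AP-1 median in macrophage-like cells stands at -1.51 and the PMN-MDSC median at -0.08.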

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

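The tests of overlap with genes of the vehicle feature table and of fibroblast markers among shifted genes were chosen after the shifts had been seen.

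Haemoglobin genes took 0.3829% of all UMIs of the ARRY-614 library and 0.0004% of those of the vehicle library, and stood out as a signal outside the comparisons that was above its level in the vehicle library (31.9% and 0.377% of kept cells had such a UMI). For the same reason Gm42418, a gene model within ribosomal RNA, stood out at 6.255% of the ARRY-614 UMIs against 0.732% of the vehicle UMIs, and its log2 ratio lay between 2.45 and 3.49 in the 7 classes compared. The unnamed cluster 15, led by histone genes with Aicda and Mef2b, genes of germinal centre B cells, held 2.279% of kept ARRY-614 cells (142 cells) and 0.879% of vehicle cells (84 cells). The unnamed cluster 29, led by Ccr3, Alox15 and Retnlg and including Prg2, an eosinophil granule protein gene, held 0.305% of ARRY-614 cells (19 cells) and 0 of 9551 vehicle cells (95% interval up to 0.039%).

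Genes shifted at least 4-fold the same way in 6 classes numbered 31 higher and 22 lower. Of the 31, 23 (74.2%) share exon sequence with a gene listed only in the vehicle feature table, against 2.36% of all 8124 genes measured, so reads that the vehicle processing dropped as ambiguous are a candidate source of these ratios. Of the 22, 6 (27.3%) are fibroblast markers, against 0.098% of all genes measured, which is consistent with less free fibroblast RNA in the ARRY-614 suspension. A further 5 of the 22 (22.7%) share exon sequence with a gene listed only in the ARRY-614 table. The rest are not on the marker list and share no exon sequence with a gene listed in a single feature table. They include Hspa1a, Atf3, Fosb, Ccl3, Amd2, Coro1b, Taf6l, Mgp, Sparc and Serping1. In B cell-like cells Mgp (-7.56), Sparc (-5.99) and Serping1 (-7.96) lay between the markers Dcn (-8.71) and Col1a1 (-5.40). In epithelial-like cells Sparc (-3.14) and Serping1 (-2.41) were lowered less than Col1a1 (-4.95). Less free fibroblast RNA may thus reach beyond the listed markers, which was not tested. Coro1b overlaps another gene, so its level is uncertain. A treatment effect on the remaining genes stays open, as does any other difference between the runs.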

How the results depend on the processing

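The largest shared cluster of a class, the non-lymphoid denominator, totals without Gm42418 and AY036118, and clustering without overlapping genes were alternatives chosen after the data had been seen. No paired analysis was possible because each group had 1 pooled library and no result came from a test. The 31 results were recomputed under 345 alternatives in all. Of these values 285 stayed within the counting interval of the reported one, 53 moved beyond it (6 of them the shares of cells with an Il1a UMI after thinning, given above) and 7 changed sign against an interval that left out 0. Clustering without overlapping genes, DESeq2 size factors, resolution 2.0 and the other gene totals moved no result beyond its interval. The values that moved follow as log2 ratios, and where no reason is given the cause was not tested.

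Over non-lymphoid cells the epithelial-like share was -1.36, and the macrophage-like and neutrophil-like shares turned to 0.185 and 0.271, because B, plasma and T cell-like cells left the denominator. With at least 1000 genes and under 10% mitochondrial UMIs, the macrophage-like share was -0.348, the neutrophil-like share -0.042, the epithelial-like cytokine median -0.707 and the PMN-MDSC median 0.069. With at least 200 genes the acinar-like share was 0.643, from a main interval that held 0. Without doublet removal the cytotoxic median was -0.596. At resolution 0.5 the myCAF median was -0.316 and Acta2 -0.271.

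With each library clustered by itself the fibroblast-like share was -3.422 and the macrophage-like share -0.176. The list medians there were -1.467 (iCAF), -0.763 (myCAF), 0.417 (apCAF, turned), -0.297 (macrophage suppressive) and -2.637 (macrophage inflammatory), and single genes were -0.497 (fibroblast-like Acta2), -3.963 (macrophage-like Il1a) and -5.65 (macrophage-like Cxcl1). In the largest shared cluster the epithelial-like cytokine median was -0.812, the suppressive median -0.197, the inflammatory median -2.051 and the PMN-MDSC median -0.445, with macrophage-like Il1a at -2.374 and Cxcl1 at -3.662.

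Without TMM factors the epithelial-like cytokine median was -0.813, the cytotoxic median -0.545 and Acta2 0.042. With equal weight per cell the medians were -0.538 (epithelial-like cytokines), -1.145 (iCAF), -0.622 (suppressive) and -0.585 (cytotoxic). In that setting single genes were -0.259 (epithelial-like Il1a), -1.159 (epithelial-like Cxcl1), -2.098 (fibroblast-like Il6), 0.202 (Acta2) and -4.25 (macrophage-like Cxcl1). Centring on exon length gave -0.738 (epithelial-like cytokines), 0.001 (myCAF, turned), -0.516 (suppressive) and 0.141 (Acta2). Without the filter on low counts the epithelial-like cytokine median was -0.836.

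With cells thinned to 1000 UMIs the medians were -0.2 (epithelial-like cytokines), 0.176 (epithelial-like NF-kB targets, turned), -1.186 (iCAF), -0.678 (myCAF), 0.042 (apCAF, turned) and -0.508 (suppressive). Single genes were 1.346 (epithelial-like Il1a, turned), -1.024 (epithelial-like Cxcl1), -0.442 (Acta2) and -4.45 (macrophage-like Cxcl1). Thinning left Il1a UMIs in 10 and 4 epithelial-like cells, so depth limits that value. It gave no value for fibroblast-like Il6 and Cxcl1. Resolution 0.5 gave none for the acinar-like share, and clustering each library by itself none for the acinar-like and endothelial-like shares.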

Other observations

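The tests by cell sex were chosen after the libraries' levels of Xist and Y-linked genes had been seen, and the other tests in this part were written before their results. A further 6 tests, of dilution, equal loss of non-immune cells, gene length, free RNA, short transcripts and cell type mix, were computed first and set aside after their values had been seen. Their values in that order were a log2 ratio of fibroblasts per macrophage of -4.67, a fibroblast minus epithelial difference of log2 ratios of -3.13, a length-centred Il1a log2 ratio of -2.93 and an Il1a level in macrophages over B cells within the vehicle library of 5.14 on the log2 scale. The remaining values were a Spearman correlation across genes of 0.34 and a lowest Gm42418 log2 ratio of 2.45, and nothing here rests on these 6 values.

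The pools differed in the sex of the mice. Cells with a UMI of Xist, the RNA of the inactive X chromosome, were 14.1% of the vehicle library and 62.3% of the ARRY-614 library, and cells with a UMI of 4 Y-linked genes were 59.8% and 21.7%. Cells with Y-linked UMIs and no Xist UMI (male) numbered 5491 and 1135, and those with the reverse (female) 1122 and 3663. Within the ARRY-614 library, macrophage-like cells had Il1b at 124 CPM (without TMM factors) in male and 318 in female cells, and neutrophil-like Il1a was at 15.003 and 54.1. In the vehicle library these were 1072 and 805, and 212 and 126. The log2 ratio of macrophage-like Il1b was therefore -3.11 (-3.20 to -3.03) in male and -1.34 (-1.39 to -1.30) in female cells. That of neutrophil-like Il1a was -3.82 (-4.46 to -3.25) and -1.22 (-1.63 to -0.81), against -2.73 in the whole class, also without TMM factors. Male and female cells of a pool come from different mice, so differences between them hold those between mice as well as those between sexes. The labels do not give the sex of the animals.

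The unnamed cluster 22, led by Cxcl13, Calca and Enpp2, held 1.43% of vehicle cells (137 cells) and 0.048% of ARRY-614 cells (3 cells). Granule genes of immature neutrophils (Camp, Ngp, Ltf) led the neutrophil-like cluster 18, which held 2.63% of the class in the vehicle library and 9.50% in the ARRY-614 library. Interferon-induced genes (Ifit3, Ifit3b, Ifit2) led the B cell-like cluster 26, with 6 and 39 cells, and the macrophage-like cluster 20 (Rsad2, Cxcl10, Ifit2), with 105 and 60 cells.

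The ARRY-614 library held few fibroblast-like cells. Removal by the cell filters is argued against, since the log2 ratio of collagen and proteoglycan UMIs over all barcodes was -4.83 (-4.84 to -4.81). Lysis of fibroblasts that left their RNA in the loaded suspension is argued against as well. The level of these UMIs in B and T cell-like barcodes had a log2 ratio of -5.83 (-6.07 to -5.60). The sex mix did not account for the low share either, with a ratio of -5.76 (-7.10 to -4.67) in female cells and -5.92 (-8.97 to -4.06) in male cells, from 7 and 2 ARRY-614 fibroblast-like cells. A treatment effect on fibroblasts, tissue from another part of the tumour, incomplete dissociation, and lysis with the RNA lost before loading stay open as untested hypotheses.

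Il1a and Cxcl1 were lower in macrophage-like and neutrophil-like cells of the ARRY-614 library. Within the largest shared cluster the log2 ratio of Il1a was -2.37 (-2.60 to -2.15), which argues against the cluster shares at resolution 1.0 as the whole reason. At resolution 2.0, a cluster led by Rgs1 and Syngr1 held 462 vehicle and 27 ARRY-614 cells. Another, led by Cx3cr1 and Fcrls, held 103 and 309. These genes also lead the largest shared cluster, so a finer mix of cells stays open. Part may also come from cluster 7, which has Cxcl1 and Il1a among its leading genes and held 24.6% and 7.55% of the class. The sex mix is argued against for macrophage-like Il1a by ratios of -3.25 (-3.42 to -3.07) in female and -3.50 (-3.85 to -3.17) in male cells, while the unlike neutrophil-like ratios by sex given above leave the size of that difference open. Less handling stress during dissociation of the ARRY-614 tumours may contribute, since immediate early genes had a median of -1.51 (-1.53 to -1.48) in macrophage-like cells. Those genes also lie downstream of p38 MAPK signalling, so handling and treatment both stay open as hypotheses, and so does mouse-to-mouse variation.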
